A study of Mus musculus with 4 samples.

How the data were processed

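Poly(A)-selected RNA from telencephalic tissue of mouse embryos at embryonic day 13 was sequenced in 4 libraries, 2 control and 2 Pd1CKO, per the labels. The submitters' processing notes name the mm10 genome build and FastQC, fastp, HISAT2, TopHat, StringTie and featureCounts, with no versions, roles or order; whether counting used strand is not given in the sources used here. The deposited tables hold 1 value per gene and library with no unit in the header. These values were read as FPKM made by the authors, because they are not whole, sum to 307189, 294863, 276084 and 275598 in control 1, Pd1CKO 1, control 2 and Pd1CKO 2, and are whole multiples of 1 step per library once multiplied by gene length. A second deposited table holds, per gene, the ratio of Pd1CKO to control for each pair, made by the authors from the FPKM values without a pseudocount, and 867 of its pair 2 entries are division errors. That table keeps 21532 of the 30637 genes, with a minimum of 0.06121 FPKM in Pd1CKO 1, while the highest Pd1CKO 1 value left out where both libraries were above 0 was 0.0611. A further deposited table lists the 1714 genes of it with a pair 1 ratio above 2. The deposited table of pair 1 alone, with 27911 genes, holds the same FPKM values (largest difference 0) and was not used further.

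Sequencing depth was recovered from the FPKM steps. FPKM was multiplied by the exon-union length of each gene in Gencode M21, in which 99.8% of the genes were found, 95.8% with the same coordinates. The implied depth was 18570000 fragments in control 1, 18740000 in Pd1CKO 1, 16200000 in control 2 and 18100000 in Pd1CKO 2, and 97.3% to 97.5% of the values below 200 fragments came out whole within 0.1. Counting intervals of a fold are exact 95% intervals (Clopper-Pearson, conditional on the summed fragments of the 2 libraries), and a value of 0 was bounded by 3 fragments. Intervals and bounds cover counting error only, since PCR copies cannot be told apart without molecular identifiers. All 8 housekeeping genes examined were above 0 in every library.

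The comparison of Pd1CKO with control used limma 3.58.1 in R 4.3.3 with an intensity-dependent prior (limma-trend) on log2(FPKM + 1), for the 13927 genes with a mean of at least 1 FPKM, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate those of weakly expressed genes. Gene lists were tested with camera from limma, two-sided, with a preset correlation of 0.01 and adjustment over the 24 of 31 lists that had at least 5 tested members. An estimated correlation and fry were run beside it. With an estimated correlation camera rests on the residual degrees of freedom, which are few with 4 libraries, so a list can hardly pass whatever its shift. Fry rests on them as well, and it was not run on the simulated data described below. Within each pair, list medians were compared with 10000 random lists matched on mean expression in 20 bins, and 95% intervals came from 2000 bootstrap draws over members. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the pair values and figures, and BLAST 2.17.0 for the search for near-identical transcripts.

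The design, the gene lists, the tests and the rule for naming genes were fixed before the data were examined. The rule named the target gene; the genes past the threshold, or where too few passed, the 6 with the smallest p-value in each direction, leaving out predicted genes and pseudogenes; up to 4 members with the smallest p-value of each list described; and the 5 sex-linked genes. Genes outside this rule are said to have been chosen after their values were seen. The design foresaw a count test, and the limma fit on FPKM used here is its stated replacement for FPKM tables. The limma fit was tested on simulated data built on these libraries, with 200 changed genes per run in 5 runs and the same spread beyond counting for all genes of a pair. With the number effect of the data it recovered 0% of 2-fold and 0% of 4-fold changes, and without that effect 86.8% and 99.6%. In the same runs camera called the changed list of 20 genes in 5 of 5 runs and the unchanged list in 0 of 5. These lists were drawn at random, the changed one with every member raised 2-fold or 4-fold, and were judged at an unadjusted p under 0.05. Most real lists shifted less, and members of many moved together with replicate number. The runs therefore give neither the power nor the false-call rate of camera for the real lists.

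The alternatives were the replicate number as a block, other pseudocounts, filters and scalings, each library left out in turn, hemoglobin and mitochondrial genes left out, and other thresholds. After the data were seen, limma-voom on recovered fragments (at least 10 in at least 2 libraries), protein-coding genes alone (11784), a robust prior, and removal of trends with gene length and GC content (loess, span 0.5) were added. The values of every library were used, since the unused table of pair 1 alone only repeats them. The design foresaw p-value columns only where present, and the columns read here held FPKM values and ratios of FPKM.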

Results

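RNA-seq was carried out on telencephalic tissue, the part of the embryonic forebrain that forms the cerebral cortex and basal ganglia, from C57BL/6 mouse embryos at embryonic day 13. The 4 libraries comprised 2 controls (control 1 and control 2) and 2 conditional knockouts of Pd1 (Pd1CKO 1 and Pd1CKO 2). The controls are named wild type in the sample titles and Pd1fl/fl, a floxed genotype, in the design text. The study asked how Pd1 affects the proliferation and differentiation of neural progenitors. Expression was given as FPKM, fragments scaled by exon length and library depth. The values implied 18570000 counted fragments in control 1, 18740000 in Pd1CKO 1, 16200000 in control 2 and 18100000 in Pd1CKO 2. The labels do not say whether the embryos came from separate litters or batches, so p-values measure only the spread between these samples. Libraries that share a number are called pair 1 and pair 2. The log2 ratio of Pd1CKO to control on the log2(FPKM + 1) scale is given within each pair beside the pooled values, and 2 values given for a pair are in the order control, Pd1CKO.

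Pd1 was read as Pdcd1, the gene of the inhibitory receptor PD-1 known from T lymphocytes (ENSMUSG00000026285, mm10 chromosome 1, 94038305 to 94052553, minus strand). Pdcd1 was detected in 1 of the 4 libraries. It was listed at 0 in control 1 and Pd1CKO 1, at 0.416 FPKM in control 2, where this corresponds to 13 fragments, and at 0 in Pd1CKO 2. A count of 3 fragments, the upper limit that 0 allows, would be 0.084 FPKM in control 1, 0.083 in Pd1CKO 1 and 0.086 in Pd1CKO 2. Pdcd1 lay below the expression filter, and since control 1 was at 0 as well, its level did not check the genotype labels. Which exons the floxed alleles remove is not given in the sources used here. Of the 14 genes of the PD-1 axis list, 3 reached a mean of 1 FPKM, too few for a list test. Among these, Ptpn11, which encodes the phosphatase SHP2, was at 17.3 FPKM in control 1, 24.6 in Pd1CKO 1, 24.7 in control 2 and 23.0 in Pd1CKO 2. The T lymphocyte list had 1 gene above the filter.

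The 5 sex-linked genes separated Pd1CKO 2 from the other libraries. Xist, the RNA of the inactive X chromosome, was at 34.7 FPKM in control 1, 61.2 in Pd1CKO 1, 54.0 in control 2 and 0.003 in Pd1CKO 2. The Y-linked genes were expressed in Pd1CKO 2 alone, with 9.48 FPKM for Ddx3y, 19.2 for Eif2s3y, 3.42 for Kdm5d and 2.04 for Uty, and no more than 0.015 FPKM elsewhere. Pair 2 thus set a library with Y-linked expression against one without it, and pair 1 did not.

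The libraries differed more by replicate number than by genotype. The first principal component of log2(FPKM + 1) held 81.6% of the variance and set control 1 and Pd1CKO 1 apart from control 2 and Pd1CKO 2. Pearson correlations across the 13927 tested genes were 0.978 within pair 1, 0.987 within pair 2 and 0.912 to 0.916 between libraries of different number. With limma, a contrast of number 2 against number 1 placed 2304 genes higher and 2573 lower at an adjusted p under 0.05, against 0 and 0 for genotype. The progenitor genes Sox2, Nes and Emx1, named after their values were seen, stood at 149, 129 and 54.1 FPKM in control 1 and at 53.3, 54.5 and 13.8 in control 2. Their values in Pd1CKO 1 were 143, 138 and 65.2 FPKM, and in Pd1CKO 2 they were 50.5, 52.3 and 16.3. Across genes, the log2 ratio of pair 1 had a Spearman correlation of 0.305 with gene length and -0.33 with GC content, while the values for pair 2 were 0.016 and -0.058.

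**Figure D1:**
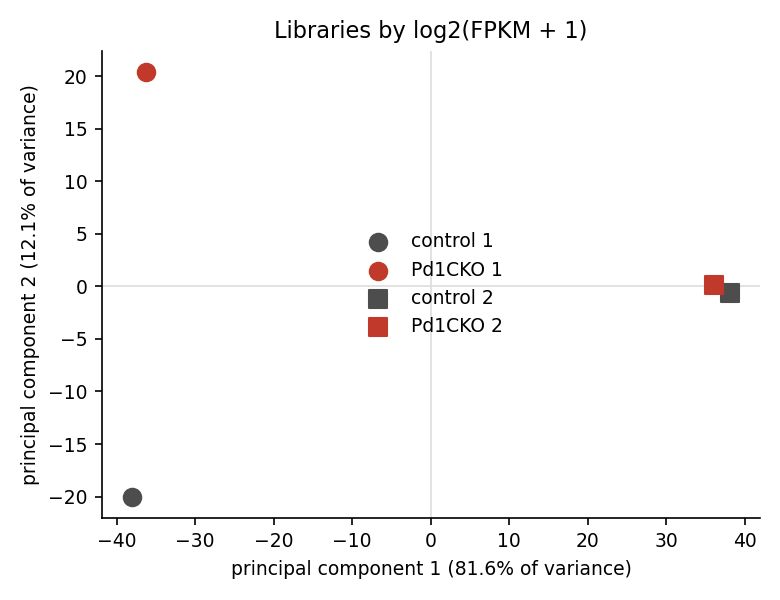
Position of the 4 libraries on the first and second principal components of log2(FPKM + 1), in component units, with the percentage of variance on each axis; grey marks control, red marks Pd1CKO, circles are replicate 1 and squares replicate 2. The first component (81.6%) runs from -38 for control 1 and -36.2 for Pd1CKO 1 to 38.1 for control 2 and 36.1 for Pd1CKO 2, and the second (12.1%) separates control 1 from Pd1CKO 1.

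The gene-level comparison asked which transcripts differ between Pd1CKO and control. No gene passed an adjusted p of 0.05 in limma, and 47 genes had an unadjusted p under that value, 32 higher and 15 lower in Pd1CKO. The split of control 1 and Pd1CKO 2 against the other libraries, which follows neither genotype nor number, gave 49. Both fits hold the number effect in their residual spread, which lowers both counts, so their likeness does not show that genotype has no effect. The 6 genes with the smallest p-values in each direction follow, and none of them passed. Tdg, the thymine DNA glycosylase of base excision repair and DNA demethylation (chromosome 10, 82629828 to 82650799), averaged 18.1 ± 0.529 FPKM in control and 34.6 ± 1.38 in Pd1CKO (SD, n = 2). Its log2 fold change was 0.90 ± 0.18 (SE) with an adjusted p of 0.9998 in limma. The exact 95% counting intervals of the fold were 1.89 to 2.12 in pair 1 and 1.71 to 1.93 in pair 2. Trpm3, a calcium-permeable channel gene also expressed in the choroid plexus, had 1.07 and 2.44 FPKM in pair 1 and 0.865 and 1.97 in pair 2. Klhl11, a ubiquitin ligase adaptor, stood at 1.13 and 3.75 FPKM in pair 1 and at 2.01 and 3.35 in pair 2. The potassium channel gene Kcna3 had 0.623 and 3.42 FPKM in pair 1 and 0.974 and 1.66 in pair 2. Rab26os had 1.41 and 3.01 FPKM in pair 1 and 1.61 and 3.11 in pair 2. As an opposite-strand transcript it cannot be told from its partner without stranded counting. Mir670 rested on 1, 5, 0 and 3 fragments in control 1, Pd1CKO 1, control 2 and Pd1CKO 2.

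In the lower direction, Ppih, a cyclophilin of the spliceosome, had 13.2 FPKM in control 1 and 9.02 in Pd1CKO 1, and 15.9 in control 2 and 7.0 in Pd1CKO 2. Syt13, a synaptotagmin, had 16.3 and 2.33 FPKM in pair 1 and 8.65 and 4.96 in pair 2. Its log2 fold change was -1.54 ± 0.44 (SE) with an adjusted p of 0.9998 in limma. Pnoc, the precursor of the neuropeptide nociceptin, had 6.14 and 2.87 FPKM in pair 1 and 4.95 and 3.58 in pair 2. Zic4, a zinc finger transcription factor, had 8.60 and 6.34 FPKM in pair 1 and 8.57 and 4.83 in pair 2. The transcript AI606473 had 5.69 and 3.47 FPKM in pair 1 and 5.67 and 3.31 in pair 2. The transporter gene Slc10a4 had 5.55 and 3.90 FPKM in pair 1 and 5.80 and 3.75 in pair 2. Tdg and Ppih each have a processed pseudogene, Gm9855 and Gm11585, at least 99.2% identical over the aligned transcript. Their levels are therefore uncertain by what the counting assigned to each copy. Summed with Gm11585, the fragments of Ppih scaled to library depth had log2 ratios of 0.173 in pair 1 and -0.446 in pair 2, so the lower value in pair 1 did not hold for the sum. Summed with Gm9855, those of Tdg had log2 ratios of 0.62 in pair 1 and 0.441 in pair 2, against 1.004 and 0.864 for Tdg alone. With limma-voom on fragments recovered from the FPKM values, a test chosen after the data were seen, 0 genes passed as well. In simulated data with the number effect of these libraries, the same limma fit recovered 0% of genes changed 2-fold and 0% of those changed 4-fold. Without a number effect it recovered 86.8% and 99.6% with 21.2 false calls per run. The count of 0 therefore does not bound the number of genes that differ.

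**Figure D2:**
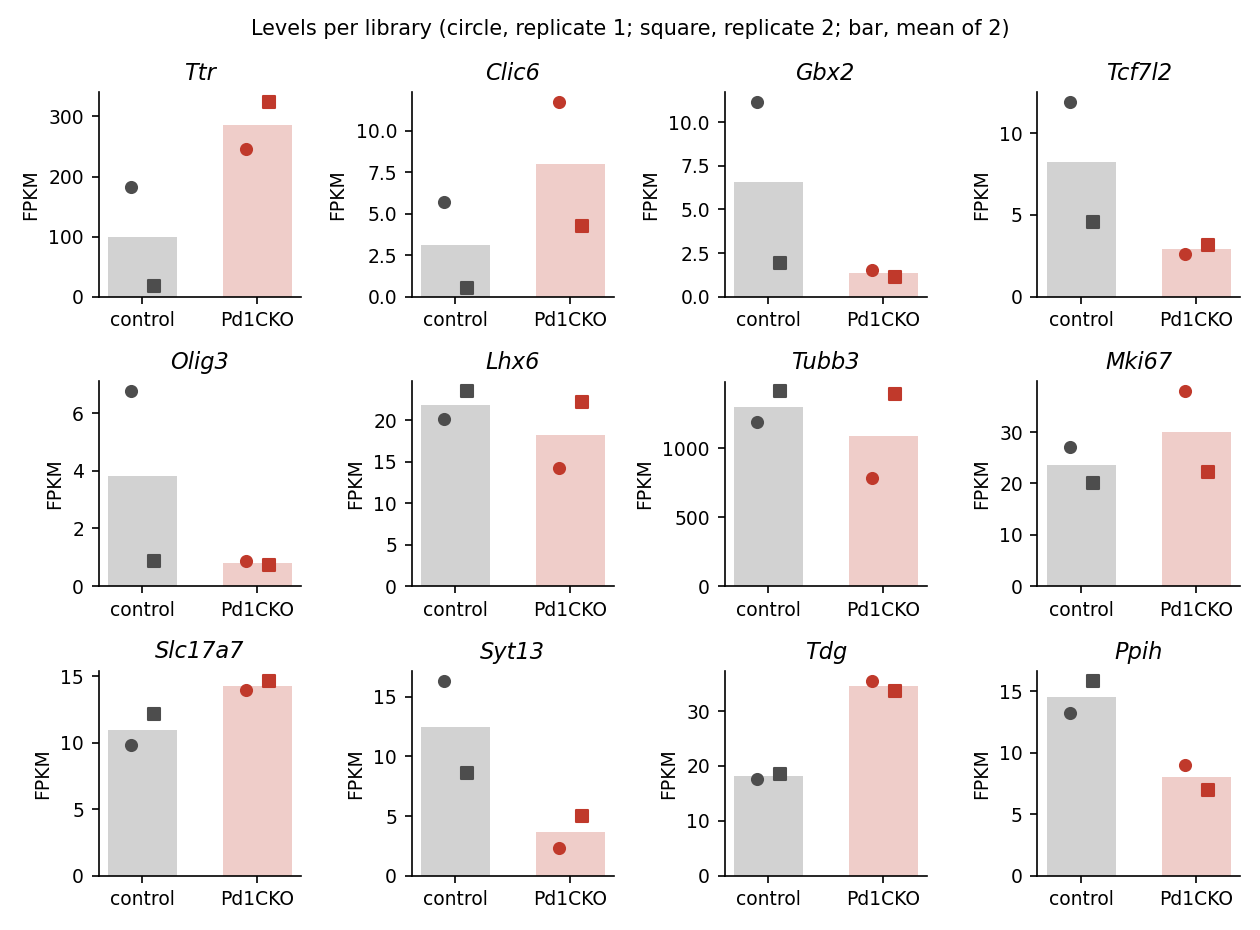
FPKM of 12 genes in each library; circles are replicate 1, squares replicate 2, and bars the mean of 2 libraries in control (grey) and Pd1CKO (red), with a separate axis from 0 for each gene. Tdg is at 17.7 and 18.5 in control and 35.5 and 33.6 in Pd1CKO, while Ttr is lowest in control 2 (17.0) and Gbx2 is highest in control 1 (11.2).

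For the proliferation of progenitors, the lists of radial glia, intermediate progenitors and cell cycle phases were compared. None of them passed in camera, limma's test of a list against all other genes, with a preset correlation of 0.01 between genes. The G2/M list had 19 of 24 members higher in Pd1CKO 1 than in control 1 and 18 of 24 higher in Pd1CKO 2 than in control 2. Its median log2 ratios were 0.178 (95% bootstrap interval over members 0.048 to 0.337) and 0.04 (0.013 to 0.108), with a camera adjusted p of 0.204. Mki67, the proliferation marker Ki-67, stood at 27.1 and 38.0 FPKM in pair 1 and 20.1 and 22.2 in pair 2. The mitotic kinase gene Bub1 had 12 and 16 FPKM in pair 1 and 7.70 and 8.49 in pair 2. The values of the kinase gene Ttk were 6.17 and 7.76 FPKM in pair 1 and 4.12 and 4.92 in pair 2. Those of the centromere protein gene Cenpf were 7.47 and 10.1 FPKM in pair 1 and 4.69 and 5.25 in pair 2. The S phase list had median log2 ratios of 0.053 in pair 1 and -0.009 in pair 2 with an adjusted p of 0.981. Its replication gene Mcm4 had 24.9 and 29.0 FPKM in pair 1 and 15.4 and 16.9 in pair 2. Of the 22 radial glia genes, which mark the neural stem cells, 16 were higher in pair 1 (median 0.200) and 11 in pair 2 (median -0.002), with an adjusted p of 0.549. Among them, Gli3, a transcription factor of the Hedgehog pathway, had 7.18 and 11 FPKM in pair 1 and 6.05 and 6.05 in pair 2. The intermediate progenitor list, with Eomes at 40.8 and 51.8 FPKM in pair 1 and 51.4 and 48.7 in pair 2, had medians of -0.029 and 0.021 and an adjusted p of 0.848. The cell cycle exit and p53 list had medians of 0.077 and 0.064 and an adjusted p of 0.719. No member of any list passed in limma over all genes, and 0 passed when adjusted over the list alone, without a replicate block.

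For differentiation, the postmitotic neuron list had 17 of 22 members lower in Pd1CKO 1 than in control 1, with a median log2 ratio of -0.194 (95% bootstrap interval -0.290 to -0.042). In pair 2, 10 of 22 were lower, with a median of 0.027 (-0.044 to 0.05). The list did not pass in camera (adjusted p = 0.0784). Tubb3, the neuronal beta-tubulin, stood at 1190 FPKM in control 1 and 784 in Pd1CKO 1, and at 1411 in control 2 and 1389 in Pd1CKO 2. Gap43, a growth cone protein gene, had 229 and 145 FPKM in pair 1 and 352 and 325 in pair 2. The intermediate filament gene Ina had 135 and 106 FPKM in pair 1 and 157 and 144 in pair 2. The cortical layer neuron list had 14 of 19 members higher in pair 1 (median 0.217) and 14 in pair 2 (median 0.049), of which 10 were higher in both, with an adjusted p of 0.0676. Slc17a7, the vesicular glutamate transporter gene, had 9.80 and 13.9 FPKM in pair 1 and 12.1 and 14.7 in pair 2. The upper-layer factor Cux2 had 8.79 and 10 FPKM in pair 1 and 10.5 and 12.6 in pair 2. Bhlhe22 had 23.3 and 33.3 FPKM in pair 1 and 30.5 and 31.2 in pair 2. The Cajal-Retzius list, for the earliest cortical neurons, had medians of -0.206 and -0.087 and an adjusted p of 0.146. Lhx5, one of its members, was at 15.7 and 7.74 FPKM in pair 1 and 3.31 and 2.83 in pair 2.

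Markers of regions inside and beside the telencephalon gave the 3 lists that passed in camera, and none passed with a correlation estimated from the data (adjusted p = 0.929 for each). With 4 libraries that version can hardly call a list whatever its shift, so it does not decide between them. The diencephalon and hypothalamus list was lower in Pd1CKO (adjusted p = 0.000142, and 0.929 with an estimated correlation), with 8 of 8 members lower in pair 1 and a median log2 ratio of -0.968 (95% bootstrap interval -2.05 to -0.385). In pair 2, 5 of 8 were lower and the median was -0.069 (-0.413 to 0.246). Its thalamic genes Gbx2 and Tcf7l2 stood at 11.2 and 11.9 FPKM in control 1, at 1.54 and 2.60 in Pd1CKO 1, at 1.93 and 4.56 in control 2 and at 1.12 and 3.17 in Pd1CKO 2. Olig3 had 6.76, 0.876, 0.864 and 0.746 FPKM in the same order of libraries. The ventral telencephalon list, for the progenitors and interneurons of the ganglionic eminences, was lower (adjusted p = 0.0162, and 0.929 with an estimated correlation), with 18 of 20 members lower in pair 1 and a median of -0.503 (-0.628 to -0.312). In pair 2, 13 of 20 members were higher and the median was 0.037 (-0.053 to 0.169). Lhx6, a factor of migrating cortical interneurons, had 20.2 and 14.3 FPKM in pair 1 and 23.5 and 22.2 in pair 2. Lhx8 and Isl1, factors of cholinergic and striatal neurons, had 15.6 and 15.1 FPKM in control 1, 9.68 and 11.2 in Pd1CKO 1, 8.27 and 12.9 in control 2 and 7.61 and 11.7 in Pd1CKO 2. The progenitor factor Gsx1 had 3.86 and 1.69 FPKM in pair 1 and 0.662 and 0.717 in pair 2. The list of the cortical hem, the dorsal midline signalling centre, and the choroid plexus, which secretes cerebrospinal fluid, was higher (adjusted p = 0.00139, and 0.929 with an estimated correlation). Of its 14 members, 13 were higher in pair 1 and 12 in pair 2, with medians of 0.437 (0.299 to 0.588) and 0.169 (0.075 to 1.09). Ttr, the choroid plexus transthyretin gene, had 182 FPKM in control 1, 246 in Pd1CKO 1, 17.0 in control 2 and 325 in Pd1CKO 2. The exact 95% counting interval of its fold was 17.1 to 21.4 in pair 2. Clic6 had 5.74, 11.8, 0.552 and 4.29 FPKM in the same order of libraries, Kcne2 had 6.52, 9.52, 0.384 and 6.41, and Folr1 had 1.59, 1.98, 0.134 and 2.43. The difference between the pairs in each list was not tested.

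For each of these 3 lists fry, limma's rotation test, gave an adjusted p of 0.988. Over all lists its smallest unadjusted p was 0.468, for the interferon response. Fry also rests on the few residual degrees of freedom, which hold the number effect here, so its outcome does not count against the lists. Leaving out control 1 put the ventral list upward in Pd1CKO (adjusted p = 0.00345) and the diencephalon list upward (0.494), and leaving out Pd1CKO 2 ended the calls of both (0.855 and 0.0924). The hem list was downward without control 2 (0.584) or without Pd1CKO 1 (0.48). Without the filter on low values the ventral list had an adjusted p of 0.192. Leaving out any 1 library sets replicate number partly against genotype, and 9 to 15 of the 24 lists then passed. The midbrain and hindbrain list had 3 members above the filter, the eye pigment list 1 and the epidermis and muscle list 4, too few to test.

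**Figure D3:**
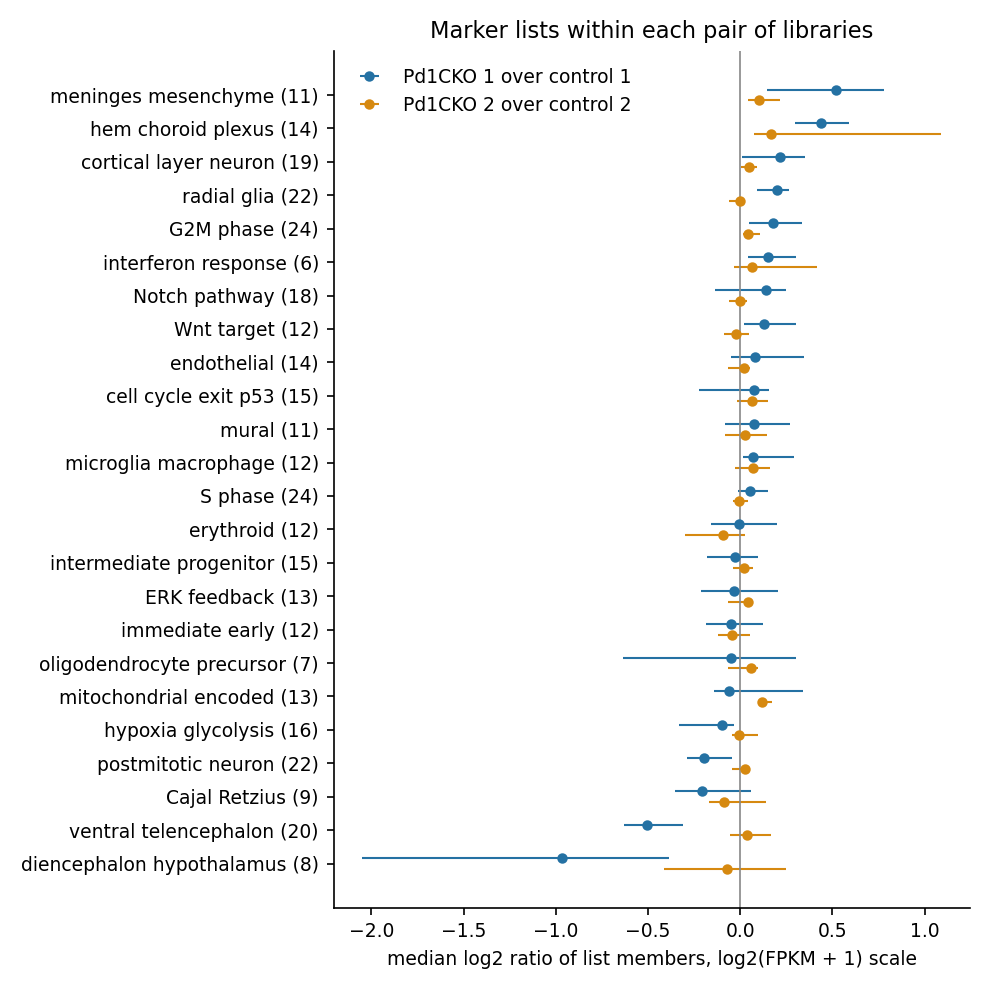
Median log2 ratio of the tested members of 24 gene lists, on the log2(FPKM + 1) scale, in pair 1 (blue, Pd1CKO 1 over control 1) and pair 2 (orange, Pd1CKO 2 over control 2); bars are 95% bootstrap intervals over members, which cover neither library nor animal variation, and numbers in brackets are tested genes. The diencephalon list lies at -0.968 in pair 1 and -0.069 in pair 2 and the ventral telencephalon list at -0.503 and 0.037, while the hem and choroid plexus list lies above 0 in both.

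Lists for other cell types did not pass. The meninges and mesenchyme list, the tissue that wraps the brain, had 10 of 11 members higher in pair 1 (median 0.522) and 9 of 11 in pair 2 (median 0.103), with a camera adjusted p of 0.204. Its collagen gene Col1a2 had 6.29 and 12.3 FPKM in pair 1 and 0.353 and 0.573 in pair 2. Dcn, the gene of the matrix protein decorin, had 2.94 and 4.67 FPKM in pair 1 and 0.434 and 0.539 in pair 2. Microglia and macrophage genes had medians of 0.068 and 0.068 (adjusted p = 0.229), with Tyrobp at 2.10 and 3.44 FPKM in pair 1 and 2.13 and 2.32 in pair 2. After removal of trends with gene length and GC content, chosen after the data were seen, their medians were 0.258 (0.148 to 0.321) and 0.059 (-0.043 to 0.146). The adjusted p was 0.702 for the endothelial and for the oligodendrocyte precursor list, 0.719 for the mural list and 0.848 for the erythroid list. Among pathways, the camera adjusted p was 0.332 for the interferon response, 0.462 for Wnt targets, 0.549 for the Notch pathway and 0.883 for ERK feedback. Among cell states it was 0.166 for hypoxia and glycolysis, 0.607 for immediate early genes and 0.549 for the mitochondrially encoded genes. Notch2, a receptor of the Notch pathway, had 6.40 and 12.2 FPKM in pair 1 and 7.20 and 8.58 in pair 2. The Wnt target Tnfrsf19 had 13.1 and 24.8 FPKM in pair 1 and 15.8 and 13.9 in pair 2. The median over both pairs was above 0 while camera's direction was downward for the S phase, intermediate progenitor, ERK feedback and oligodendrocyte precursor lists. The mitochondrial genes mt-Atp8 and mt-Nd4l overlap their neighbours on the same strand, so their counts are uncertain. The values of mt-Nd4l were 7.43 and 22.8 FPKM in pair 1 and 9.56 and 11.5 in pair 2. The replication histone list had 2 members above the filter and the sex-linked list 3.

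The pairs, which share no library, were then set against each other. Across 13927 genes the log2 ratios of pair 1 and pair 2 had a Pearson correlation of 0.006 (95% bootstrap interval over genes -0.052 to 0.064) and a Spearman correlation of 0.052. The sign was the same for 51.8% of genes. Genes are not independent replicates. The standard deviation of the log2 ratio was 0.34 in pair 1 and 0.25 in pair 2. Among the genes with the same direction in both were Tdg, named above, and Sarnp, an mRNA export factor chosen after its values were seen, which had 34.9 and 18.5 FPKM in pair 1 and 21.2 and 10.3 in pair 2. Without the filter on low values the Pearson correlation was 0.009, and among protein-coding genes outside the sex-linked list, a set chosen after the data were seen, it was 0.067 (0.04 to 0.099).

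**Figure D4:**
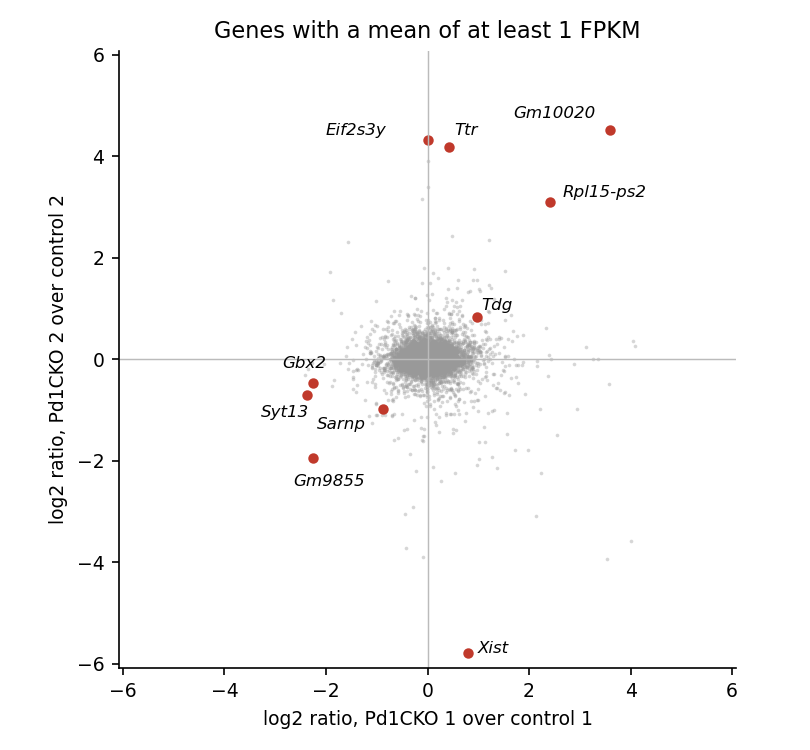
Log2 ratio of Pd1CKO to control on the log2(FPKM + 1) scale in pair 1 (horizontal axis) and pair 2 (vertical axis) for the 13927 genes with a mean of at least 1 FPKM, each a grey point, with 10 genes in red named after their values were seen. The cloud has a Pearson correlation of 0.006, Tdg lies at 0.96 and 0.83, and Xist (-5.78 in pair 2) and Eif2s3y (4.31 in pair 2) mark the sex difference of pair 2.

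The authors' deposited table gives one FPKM ratio of Pd1CKO to control per pair and was described without a test. Among its 13892 genes with a mean of at least 1 FPKM, the authors' deposited table had 290 genes at least 2-fold higher and 205 at least 2-fold lower in pair 1, and 139 and 157 in pair 2. Of these, 20 genes of the authors' deposited table were at least 2-fold higher in both pairs and 18 at least 2-fold lower in both, where independent lists of those sizes would share 2.9 and 2.3. In opposite directions, 48 genes of the authors' deposited table were past 2-fold, where independent lists would give 5.3. With no floor on the mean FPKM, chosen after the data were seen, the authors' deposited table had 220 genes higher and 171 lower in both pairs and 382 in opposite directions. For these, independent lists would give 76.3, 56.7 and 142.2. The table had kept genes with at least 0.06121 FPKM in Pd1CKO 1 but as little as 0.0087 in control 1, so genes low in Pd1CKO 1 were left out of its ratios more often than genes low in control 1.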

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

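The voom, protein-coding, robust-prior, trend-removal and sex-linked alternatives, the block with an estimated correlation, fry or no filter, and the floor-free ratios were chosen after the data were seen. With the replicate block, limma called 3 genes higher (Gm10020, Rpl15-ps2, Gm11585) and 2 lower (Gm9855, Gm10182) in Pd1CKO, all processed pseudogenes, and 7 lists, adding neurons, cortical layers, G2/M and meninges, each at an adjusted p of 0.78 once the correlation was estimated. The hem list lost its call at an estimated correlation of -0.0549 (unadjusted camera p 7.02e-08 to 0.11), so not through correlation between members. For the diencephalon (1), ventral (0.8) and meninges (0.6364) lists it may have added to the loss. With 4 libraries, camera so run says little about the lists. Adjusted over its list alone, no list member passed without the block, and with it Clic6, Kcne2, Hba-a2 and mt-Atp8 passed upward and Gbx2 and Tcf7l2 downward. With the block, 31 genes were higher and 26 lower in voom on recovered fragments, 62 and 44 among protein-coding genes, 5 and 7 with a robust prior, and 0 and 0 without the filter on low values (smallest adjusted p 0.916). Among protein-coding genes the block pools the spread over all genes, so a gene that moved in 1 pair can pass. In simulated data the block recovered 83.1% of 2-fold and 97.9% of 4-fold changes with 29 false calls per run beside 79.6 and 92.8 true ones. Deviations from the group means correlated at 0.799 between same-numbered libraries, but 2 pairs whose labels name no litter or batch share only a number. All other settings run, each library left out included, called 0 genes in either direction, as did an adjusted p under 0.1 without the block.

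The 3 lists that passed became 0 with an estimated correlation, 0 with fry, 0 with fry and the block, 0 with the block and an estimated correlation, 5 among protein-coding genes, 9 among these with the block, and 9 with the block after removal of length and GC trends. That removal added the microglia (adjusted p = 0.0197) and Cajal-Retzius (0.0499) lists to the 7 of the block, and was not run with an estimated correlation. With 1 library left out the count ranged from 9 to 15. The adjusted p of the ventral, hem and diencephalon lists was 0.929 each with an estimated correlation and 0.78 each with the block as well, 0.988 each with fry, and 0.774, 0.518 and 0.759 with fry and the block. Both tests can hardly call a list with 4 libraries, so these values do not count against the lists. Without the filter the ventral list had 0.192. With 1 library left out, the ventral list ranged from 4.47e-09 to 0.855 and was reversed without control 1 (0.00345), the hem list ranged from 1.06e-14 to 0.584 and was reversed without control 2 or Pd1CKO 1 (0.48), and the diencephalon list ranged from 6.46e-13 to 0.494 and was reversed without control 1. These fits assume that the lone library varies like the other arm and mix replicate number with genotype by construction. Beyond that the cause was not tested.

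The correlation of the pairs was 0.067 among protein-coding genes without the sex-linked ones, and the authors' ratios without a floor had 220 genes higher and 171 lower in both pairs and 382 in opposite directions. Of 109 named genes tested, 58 changed sign with a library left out and 0 in another setting, and 25 passed in an alternative chosen after the data were seen. The design largely set both sign counts. A left-out library mixes replicate number with genotype, while the block, robust prior and gene filters leave log2 fold changes alone. Tdg was among the 25, with the block in voom, with a robust prior and among protein-coding genes, but did not pass with the planned block. The count-based alternatives (DESeq2, edgeR with its TMM and library-total scalings, voom on deposited counts) were not run, since the values are FPKM. The planned threshold on the authors' p-values was not applied, as no column read held any. In a library where a gene is at 0, depth bounds it at 3 fragments.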

Other observations

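The tests of S phase genes and of the near-identical copies, and the criterion by which the G2/M trend was judged, were chosen after the results they measure were seen. Removal of trends with gene length and GC content was an alternative chosen after the data were seen, with its bounds set before its own results. Libraries numbered 2 stood apart from those numbered 1 in many lists at once, and no list test was run on this contrast. In limma, the neuronal genes Dcx and Map2 were higher in number 2 by 1.21 and 0.81 on the log2(FPKM + 1) scale (adjusted p = 0.00146 and 0.00699), and the cortical projection neuron gene Neurod6 by 1.39 (adjusted p = 0.00085). The progenitor genes Hes5, Emx1, Sox2 and Nes differed by -2.57, -1.92, -1.47 and -1.31, with adjusted p of 0.00131, 0.000994, 0.000784 and 0.000944. The median over the radial glia list was -0.981, over the S phase list -0.782, over the postmitotic neuron list 0.656 and over the meninges list -1.77. Lists of other kinds were lower in number 2 as well, with -1.25 for the hem, -1.12 for the diencephalon, -0.837 for hypoxia and -0.666 for the endothelium, and the intermediate progenitor median of -0.782 had an interval of -1.5 to 0.119. Across genes this contrast had a Spearman correlation of 0.289 with gene length and -0.278 with GC content. The embryonic globin gene Hbb-y stood at 981 FPKM in control 1, 1079 in Pd1CKO 1, 101 in control 2 and 68.0 in Pd1CKO 2. These genes were chosen after their values were seen.

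Of the 9 tested genes of a choroid plexus list, 9 were lowest in control 2, with median log2 ratios of 0.433 in pair 1 and 1.60 in pair 2. That list was written after Ttr, Folr1, Clic6, Kcne2, Aqp1 and Sostdc1 had been seen, so the count describes these libraries and tests nothing. Control 2 also had the lowest value of Hmgn2, a nucleosome-binding protein gene, at 14.2 FPKM against 302 in control 1, 278 in Pd1CKO 1 and 134 in Pd1CKO 2. Part of its reads can be divided with a near-identical copy, Gm10182. Sumo2 likewise had 39.4 FPKM in control 2 against 180, 104 and 117. Both were chosen after their values were seen. The transcription factor gene Shox2, chosen likewise, had 4.91 FPKM in control 1, 0.113 in Pd1CKO 1, 0.559 in control 2 and 0.250 in Pd1CKO 2.

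Ventral telencephalon and diencephalon markers were lower in Pd1CKO 1 than in control 1, while in pair 2 the medians of these lists were 0.037 (95% bootstrap interval -0.053 to 0.169) and -0.069 (-0.413 to 0.246), and the difference between the pairs was not tested. A trend with gene length and GC content as the whole cause was argued against, since the ventral median in pair 1 was -0.503 before and -0.396 (upper 95% bootstrap bound -0.289) after its removal. Among the members named above for their small p-values, Gbx2, Tcf7l2, Olig3, Lhx8, Isl1 and Gsx1 were highest in control 1, and Lhx6 was highest in control 2. For these members the pattern thus rests on a high control 1 as much as on the level of Pd1CKO 1. Unequal content of neighbouring brain regions in the samples of pair 1 and an effect of genotype both stay open, and neither was tested beyond the values that make up the pattern.

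G2/M genes were higher in Pd1CKO in both pairs for 16 of 24 members, with a median over both pairs of 0.094 (95% bootstrap interval 0.064 to 0.224). Camera put the list downward without control 2 or without Pd1CKO 1, and upward without control 1 or without Pd1CKO 2. The list median was -0.704 for number 2 against number 1, so these fits mix replicate number with genotype and do not test the rise within pairs. Length and GC trends as the whole cause were argued against, since after their removal the median was 0.091 (0.048 to 0.135) and camera with the block gave an adjusted p of 0.00711 against 0.0143 before (0.78 before with an estimated correlation), although the bound of 0.1 set in advance, which lay above the uncorrected median, was not met. In pair 2 alone the median went from 0.04 (0.013 to 0.108) to 0.021 (0.001 to 0.085), so a part played by such trends there stays open. A higher share of cycling cells, the candidate explanation closest to the study's question, would raise S phase genes as well, and their median relative to all tested genes was 0.002. That value does not separate a small rise from none, and the sex difference of pair 2 was not tested against either.

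The genes called with the replicate block were processed pseudogenes, among them Gm9855, whose fragments went from 612 to 112 in pair 1 and from 665 to 177 in pair 2, and the Rpl15 copies Gm10020 and Rpl15-ps2, together from 51 to 686 and from 21 to 734. Whether reads were divided differently between a gene and its near-identical copies stays open. The sum over copies and source changed under 0.1 times as much as the copies in both pairs in 1 of 4 families, that of Rpl15 (0.034 and 0.014), where the source dominates the sum and fixes this outcome, against 0.107 and 0.23 times for Ppih, 0.252 and 0.213 for Tdg and 0.103 and 2.28 for Hmgn2. For Tdg, a transfer of counted fragments from Gm9855 alone was argued against, as Tdg gained 3.55 and 2.6 times what Gm9855 lost, in fragments scaled to library depth, in pair 1 and pair 2 (95% intervals from resampled counts 3.11 to 4.04 and 2.25 to 3.02). This holds only if fragments that match both copies were counted, which the sources used here do not state. If they were dropped, gain and loss need not balance, and division with Gm9855 stays open. A strain variant inside the copies was not tested and stays open, so the higher Tdg level remains a hypothesis to follow up.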
